A study of Oryza sativa with 36 samples.

How the data were processed

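RNA abundance was measured on an Affymetrix rice array in leaf and root of 3 rice genotypes, 9311, LYP9 and PA64s. From background knowledge and not from the labels, LYP9 is a hybrid and 9311 and PA64s are its parents. The labels give 36 arrays in 12 groups of 3, 1 group for each genotype, tissue and nutrient state. Per the labels, seedlings spent 5 days in a nutrient soil mix, and 15 seedlings of each variety were then set in each of 12 barrels of poor soil. When they were 14 days old, 10 g urea and 10 g compound fertiliser went to 6 of the barrels, the nutrient-sufficient state, which the labels also call heterotic. The other barrels are the nutrient-deficient state, which the labels call non-heterotic. RNA was taken with Trizol, purified on RNeasy columns and labelled with biotin as complementary RNA. The labels do not say whether replicates 1 to 3 of a group came from different barrels or plants, so the p-values below measure only the spread between these samples.

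The deposited table holds 57381 probe sets by 36 arrays. The authors deposited linear array intensities with a floor of 1, as their range shows, and how they were scaled is not given in the sources used here. The submitters' processing notes name RMA and affy, but not their role or versions, and RMA usually gives log2 values. Each value was therefore transformed to log2 once, with no further scaling. Array medians ran from 66.96 to 75.39 intensity units in leaf and from 65.98 to 74.5 in root. Trimmed means, without the outer 2% at each end, ran from 204.3 to 240.8 in leaf and from 188.9 to 209.5 in root. Between 0 and 11 values per array sat at the floor. Pearson correlations across probe sets between arrays of 1 group ran from 0.9593 to 0.9892 in leaf and from 0.9526 to 0.9836 in root, and no arrays were identical. Read counts do not apply to arrays, and the 3 arrays per group limit the precision.

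The 187 control and reporter probe sets were left out. Of the 57194 others, 22436 carry 1 gene symbol in the annotation, 95 carry several and 34663 are not listed. The 17905 genes behind single symbols were all found by gene ID in the reference gene table, and 2457 of them have a name other than a locus number. The genome build behind the probe design is not given in the sources used here, so genes are identified by symbol and gene ID and no position is printed. A symbol names the gene that the annotation ties to a probe set, and probes may also bind related genes.

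Leaf and root were analysed apart in R 4.3.3 with limma 3.58.1. In each tissue the probe sets in the upper 60% by mean log2 value over the 18 arrays were kept, 34316 of them, above 5.753 in leaf and 5.703 in root. A mean per group was fitted with lmFit and tested with eBayes, 2-sided, with 12 residual degrees of freedom and prior degrees of freedom of 3.87 in leaf and 3.85 in root. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets kept, and every adjusted p of a gene below is of this kind. Contrasts were nutrient-sufficient minus deficient in each genotype, 9311 minus PA64s averaged over both states, and LYP9 minus the mean of the parents on the log2 scale (the mid-parent) in each state. The last contrast was that mid-parent deviation in the sufficient state minus the same in the deficient state. A probe set was outside the parental range when LYP9 was called above both parents or below both. Errors beside log2 differences are limma standard errors, and those beside group levels are SDs of 3 arrays. Where a group's mean of a named gene lay below the filter level, its change is printed as a log2 difference and not as a fold. Background signal was not analysed here, so the size of such a difference is uncertain.

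Gene lists were tested with camera from limma, 1 probe set per gene, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. A list needed 5 measured genes. Of 33 lists with 574 genes, 27 were tested in leaf and 29 in root. Their themes, loci and search words, the design, the filter, the alternatives and the rule for named genes were set before the data were examined. The annotation proved to hold symbols but no descriptions, so list members were matched by symbol afterwards, before any contrast was fitted, and a list of plastid ribosomal proteins was dropped. "Adjusted over the list alone" means that the adjustment ran over a list's own members only.

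The rule for named genes took, per contrast, called probe sets with exactly 1 named gene whose arrays did not overlap between the sides compared. From these it took up to 6 with the largest rise and up to 6 with the largest fall. Chance gives such a separation to 10% of probe sets for 3 arrays against 3. It added up to 2 called members per direction of each list passing camera at the preset correlation, and called loci of the nitrogen, phosphate, clock and tillering lists in nutrient contrasts. The separation was not required of list members. For the mid-parent contrasts its sides were LYP9 and both parents together. Genes outside the rule are marked where they appear.

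The analysis was tested on simulated data built from these arrays, with 50 probe sets changed at each of 4 sizes. Noise was drawn independently between arrays. For the LYP9 nutrient contrast, limma called 66% of log2 changes of 1 in leaf and 74% in root, and 16% and 26% of changes of 0.5. For the difference in mid-parent deviation between states it called 48% and 52% of changes of 1, and 94% in both tissues at a change of 2. For the parental contrast it called 92% and 94% at a change of 1. Between 2.33% and 8.07% of calls in these runs were false.

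Alternatives to the main analysis were array weights, no filter, a filter at the upper 40%, median centring, quantile normalization, 1 probe set per gene, replicate number as a block, all 36 arrays in 1 fit, the mid-parent on the linear scale, eBayes with trend and robust options, a change of at least 2-fold, the estimated correlation in camera, and leaving out each array in turn. The first counts had been seen before the tests of explanations were written. The values those tests measure had not, except for the items chosen after seeing the data and the clock gene test, whose bound was tightened once its value was known. Chosen after seeing the data were a replicate block within each nutrient state, the splits within replicate numbers, the contrasts of the mean nutrient response and of the parents' nutrient responses, those between leaf and root, and the comparison of other probe sets with nutrient responses of 4-fold or more. Whether replicate numbers pair the samples was settled from correlations of deviations from group means before any blocked fit, per comparison, a unit chosen once those correlations had been seen.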

Results

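Probe set intensities were compared across 36 arrays, 18 from leaf and 18 from root, in 12 groups of 3 arrays. The groups cross 3 genotypes, the hybrid LYP9 and its parents 9311 and PA64s, with both nutrient states. Per the series description, the aim was to remove background differences in the hybrid and to find those tied to the start of heterosis in early vegetative growth. The tissues separated by their marker genes. The 8 light-harvesting and photosystem genes averaged 12.49 to 13.30 log2 units over the leaf groups and 5.64 to 6.41 over the root groups. The 3 Calvin cycle genes averaged 10.18 to 10.70 in leaf and 5.14 to 5.78 in root, and 6 root-enriched genes averaged 9.01 to 9.28 in root and 6.63 to 6.78 in leaf.

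The first question is how fertiliser changed the leaf of each genotype. In 9311 leaves 7 of 9 measured chlorophyll synthesis genes were called higher in the nutrient-sufficient state, though as a list they did not pass with an estimated correlation (adjusted p = 0.411), and a gene of purine nitrogen recycling was much lower. GRXC15 (LOC4352426), a glutaredoxin, rose from 5.67 ± 0.23 to 11.39 ± 0.14 log2 units (SD, n = 3; log2 change 5.72 ± 0.32 SE, adjusted p = 1.29e-07). ALN (LOC4337428), the allantoinase that opens the ring of the purine breakdown product allantoin, was 10.9-fold lower (log2 -3.44 ± 0.22, adjusted p = 4.09e-07). Also among the largest rises were BURP2 (LOC4338119) at 32.8-fold, CIPK14 (LOC4351307), a calcium-signalling kinase, at 21.3-fold, and the dehydrin RAB21 (LOC4350454) at 20.1-fold. Among the largest falls were NAAT1 (LOC9267778), an enzyme of iron chelator synthesis, at log2 -2.17 ± 0.44, and MADS57 (LOC4330621), a MADS-box factor known to act on tillering, at -1.81 ± 0.16.

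Of 9 measured chlorophyll synthesis genes in 9311 leaves, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 change of 1.02. The list passed camera at adjusted p = 2.02e-05, but not with an estimated correlation (adjusted p = 0.411 with an estimated correlation). PORA (LOC4337415), which reduces protochlorophyllide, was 7.42-fold higher, and GluTR (LOC4349044), the entry step of the pathway, 6.28-fold. Among 8 light-harvesting and photosystem genes 5 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.00121, and adjusted p = 0.411 with an estimated correlation), including PSAG (LOC4337812) at log2 1.44 ± 0.30, whose other probe set was at 0.27 and not called. Of 11 defence genes 4 rose and 0 fell (7 and 0 adjusted over the list alone), with adjusted p = 0.000617, and adjusted p = 0.411 with an estimated correlation. The Bowman-Birk protease inhibitor RBBI3.3 (LOC9271230) in this list was 10.4-fold higher. For 17 lignin and phenylpropanoid genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0224, and adjusted p = 0.45 with an estimated correlation). Of 9 gibberellin genes 2 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0406, and adjusted p = 0.45 with an estimated correlation). Of these, KAO (LOC4339885) lost its call after quantile normalization (adjusted p = 0.0537), after median centring (0.052), with all 36 arrays (0.0703) and without any of 5 arrays (log2 0.67 to 0.86), and CPS1 (LOC4329013) without any of 3 arrays (0.93 to 1.07). Of 6 histone genes 3 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0224, and adjusted p = 0.45 with an estimated correlation). The calls of H2B.7 (LOC4324500) and H2B.10 (LOC4324495) were lost without either of 2 arrays (log2 -0.64 to -0.58) and without 1 array (-0.73). The 19 nitrogen genes did not pass as a list (adjusted p = 0.782), with 2 higher and 4 lower. Among them GDH1 (LOC4334405), a glutamate dehydrogenase, rose by log2 1.19 ± 0.26, and the nitrate transporter NRT2.3 (LOC4324249) was at -0.86 ± 0.18, a call that was lost with all 36 arrays in 1 fit.

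In total limma called 4093 of 34316 probe sets in 9311 leaves, 2731 higher and 1362 lower. The share of calls that were higher, 66.7%, changed with the scaling of the arrays. After median centring, which would also remove a true rise of many transcripts, 2022 were higher and 2589 lower. The median change of all probe sets moved by -0.12 log2 units, from 0.0577 to -0.0594, and so past 0. The count fell to 1830 without deficient replicate 1, 2488 without deficient replicate 3, 2456 without sufficient replicate 1 and 2662 without sufficient replicate 2.

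LYP9 leaves gave much the same picture among the strongest genes. GRXC15 (LOC4352426) rose 30-fold (log2 4.91 ± 0.32, adjusted p = 8.51e-07), BURP2 17.2-fold by 1 of its probe sets and CIPK14 16-fold. ALN (LOC4337428) was 9.86-fold lower, from 10.62 ± 0.32 to 7.32 ± 0.26 log2 units (SD, n = 3). Other falls were GRXC7 (LOC4338050), a second glutaredoxin, at log2 -1.85 ± 0.19, MADS26 (LOC4344493) at -1.56 ± 0.22, and the urea transporter DUR3 (LOC4349520) at -1.62 ± 0.24. GER5 (LOC4345763) rose by log2 3.60 ± 0.67.

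By list, 5 of 11 defence genes rose in LYP9 leaves and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.000262, and adjusted p = 0.463 with an estimated correlation). RBBI3.3 was 10.2-fold higher and a chitinase (LOC4348631) 2.18-fold. Of 17 lignin and phenylpropanoid genes 7 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00767, and adjusted p = 0.463 with an estimated correlation), with PAL (LOC4330034), the pathway's entry enzyme, at 3.6-fold. Its other probe sets were at log2 1.95 and 1.83, both called, and at 0.75 and 0.17, not called. Of 9 chlorophyll synthesis genes 3 rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.597 with an estimated correlation), with PORA at 4.7-fold and GluTR at 4.63-fold. The nitrogen list did not pass (adjusted p = 0.891), with GDH1 higher by log2 1.60 ± 0.26 and NRT2.3 at -1.07 ± 0.18. limma called 3037 probe sets, 2127 higher and 910 lower, a share of 70% higher that was 49.6% after median centring. Without deficient replicate 1 the count was 1492, without deficient replicate 3 it was 1364 and without sufficient replicate 1 it was 1506.

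In PA64s leaves BURP2 rose 30.3-fold (log2 4.92 ± 0.49), GRXC15 19.1-fold (log2 4.26 ± 0.32) and PORA 9.71-fold (log2 3.28 ± 0.30, adjusted p = 1.63e-05). ALN was 8.88-fold lower (log2 -3.15 ± 0.22, adjusted p = 1.7e-06). SGR (LOC4347672), which acts in chlorophyll breakdown, was at log2 -2.14 ± 0.39, and the auxin response factor ARF16 (LOC4327785) at -1.75 ± 0.28. GDH1 rose 4.91-fold, and D14 (LOC4331983), the strigolactone receptor that restrains tillering, rose 2.52-fold (log2 1.33 ± 0.24).

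For PA64s leaves, 6 of 8 light-harvesting and photosystem genes rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.00034, and adjusted p = 0.379 with an estimated correlation), such as LHCP (LOC4333359) at log2 0.78 ± 0.15 and PSAH (LOC4339593) at 0.83 ± 0.17. Of 9 chlorophyll synthesis genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.00034, and adjusted p = 0.535 with an estimated correlation). Of 6 WRKY factors 3 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.000547, and adjusted p = 0.348 with an estimated correlation), with WRKY62 (LOC4347070) at log2 -1.87 ± 0.39. Of 11 defence genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.536 with an estimated correlation). The nitrogen list did not pass (adjusted p = 0.895). limma called 2652 probe sets, 1720 higher and 932 lower, and the 64.9% share of higher calls was 45% after median centring. The count was 1160 without sufficient replicate 3, 1428 without deficient replicate 3 and 1604 without deficient replicate 2, and 4208 with the replicate number as a block.

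The leaf responses of the 3 genotypes overlapped. 9311 and LYP9 shared 1397 higher and 575 lower probe sets, where 169 and 36.1 were expected by chance. LYP9 and PA64s shared 1054 and 461, with 107 and 24.7 expected. Across probe sets, which are not independent replicates, the log2 changes of 9311 and LYP9 had a Pearson correlation of 0.844, those of LYP9 and PA64s 0.824, and those of the parents 0.787. A direct test between the parents' leaf responses called 6 probe sets, with 1169 at an unadjusted p under 0.05 and 1716 expected by chance.

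**Figure D1:**
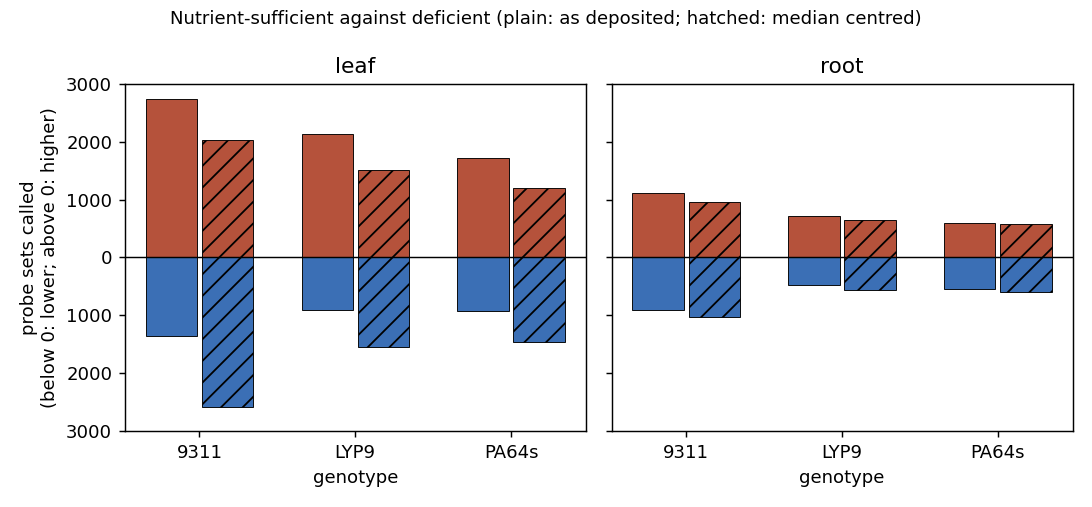
Number of probe sets called higher (above 0) or lower (below 0) in the nutrient-sufficient state for each genotype in leaf and root, as deposited (plain bars) and after median centring (hatched bars). In 9311 leaf, 2731 higher and 1362 lower calls become 2022 and 2589.

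In roots of 9311, the largest rise among the named genes was that of a chitinase and the largest fall that of ALN. The chitinase Cht1 (LOC4338719) rose from 5.60 ± 1.64 to 12.52 ± 0.38 log2 units (SD, n = 3; log2 6.92 ± 0.73 SE, adjusted p = 0.000144). NSHB1 (LOC4332166) and NSHB2 (LOC4332123), non-symbiotic haemoglobins, rose 12-fold and 8.12-fold, and CIPK14 8.51-fold. ALN was 9.87-fold lower (log2 -3.30 ± 0.24, adjusted p = 4.42e-06). The ammonium transporters AMT3;2 (LOC4334717) and AMT3;3 (LOC4329628) were at log2 -2.31 ± 0.27 and -1.55 ± 0.17, while AMT1;2 (LOC4330008) was higher by 2.13 ± 0.40.

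Of 17 iron genes in 9311 roots, 6 rose and 1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0331, and adjusted p = 0.804 with an estimated correlation). NAS1 (LOC4332608) and NAS2 (LOC4332607), which make the metal chelator nicotianamine, rose 13.7-fold and 8.56-fold, and YSL15 (LOC9268232), a transporter of chelated iron, 4.32-fold. YSL12 (LOC4336442) was at log2 -1.38 ± 0.26. Of 23 aquaporins 4 rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 0.000108, and adjusted p = 0.804 with an estimated correlation), with TIP1;2 (LOC4324303) at log2 2.15 ± 0.37. Of 13 defence genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.00891, and adjusted p = 0.804 with an estimated correlation). Of 23 cytosolic ribosomal protein genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.00147, and adjusted p = 0.804 with an estimated correlation). That gene, RPL10A (LOC9266191), was at log2 0.36 ± 0.09. It was not called after quantile normalization (0.07), after median centring (0.33), with no filter, or without deficient replicate 1 (0.34) or 3 (0.31) or sufficient replicate 1 (0.37) or 2 (0.36). In the nitrogen list, which did not pass, 3 of 20 genes rose and 3 fell. Among them AMT1;2 was at 1.99 and not called without sufficient replicate 2. limma called 2021 probe sets, 1115 higher and 906 lower. This count moved to 303 without sufficient replicate 2, 419, 952 and 728 without deficient replicates 1, 2 and 3, and 3738 without sufficient replicate 3.

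LYP9 roots shared the strongest of these changes. Cht1 (LOC4338719) rose by log2 5.56 ± 0.73 (adjusted p = 0.000615), from 5.62 ± 1.16 log2 units (SD, n = 3). NSHB1 rose 20.3-fold, from 6.73 ± 0.42 to 11.08 ± 1.02 log2 units (SD, n = 3), NSHB2 12.1-fold and CIPK14 12-fold. ALN was 9.53-fold lower (log2 -3.25 ± 0.24, adjusted p = 3.71e-06). DXPS (LOC4342614), the first enzyme of the plastid isoprenoid pathway, was at log2 -2.19 ± 0.29, and AMT3;2 and AMT2;1 (LOC4339064), both ammonium transporters, at -2.17 ± 0.27 and -1.10 ± 0.20. Of 55 auxin response genes 4 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.00722, and adjusted p = 0.174 with an estimated correlation), with a median log2 change of -0.16. The calls of ARF2 (LOC4326957) and ARF1 (LOC4350610) were each lost without any of 4 arrays (log2 -0.80 to -0.64 and -0.95 to -0.75). Of 20 nitrogen genes 3 rose and 4 fell, and the list did not pass. limma called 1188 probe sets, 720 higher and 468 lower, and 319, 521, 469 and 678 without deficient replicate 1, deficient replicate 2, sufficient replicate 2 and sufficient replicate 3.

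In PA64s roots NSHB1 rose 17.2-fold (log2 4.11 ± 0.38, adjusted p = 3.03e-05), CIPK14 10.6-fold and NSHB2 7.35-fold. The beta-glucosidase gene BGLU16 (LOC4336389) was at log2 -4.34 ± 0.64, and at -3.81 with its other probe set, also called. Its sufficient level, 4.21 ± 0.70 log2 units (SD, n = 3), is below the filter level of 5.703. BGLU30 (LOC4347441), also a beta-glucosidase gene, was 5.96-fold lower, ROMT-17 (LOC4345935), a methyltransferase gene, 10.4-fold and ALN 9.98-fold. Other probe sets of ROMT-17 were at log2 -2.63 and -2.45, both called, and at 0.16, not called. The glutathione transferase GST1 (LOC4334347) was at log2 -2.26 ± 0.36. Of 29 starch and sucrose genes 5 rose and 0 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0411, and adjusted p = 0.649 with an estimated correlation), among them TPP1 (LOC4330221) and TPP4 (LOC4330753), trehalose phosphate phosphatases, 2.51-fold and 2.63-fold higher. Of 19 lignin and phenylpropanoid genes 1 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.0411, and adjusted p = 0.744 with an estimated correlation), the laccase LAC10 (LOC4332400) at log2 -1.68 ± 0.32. Of 13 defence genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), of 7 abscisic acid and dehydration genes 1 fell and 0 rose (4 and 1), and of 55 auxin response genes 1 rose and 1 fell (2 and 6). Each of these had adjusted p = 0.0411, and adjusted p = 0.649 with an estimated correlation. All 3 defence calls were lost under some settings. Cht1 was not called with no filter (adjusted p = 0.0637), after quantile normalization (0.063), with the trend and robust options (0.0511) or without any of 5 arrays (log2 2.13 to 3.04). RBBI3.3 was not called with no filter (0.0614), after quantile normalization (0.0594) or without any of 5 arrays (1.63 to 1.97), nor Cht-1 (LOC4342115) without any of 3 (0.77 to 0.97). The auxin response gene ARF3 (LOC4327014) lost its call on leaving out any array (-0.57 to -0.42). GH3-6 (LOC4337780), an auxin response gene called higher, lost its call without 1 array (0.48). The dehydration gene rab25 (LOC4326935), called lower, lost its call without any of 3 (-0.96 to -0.93). Of 20 nitrogen genes 4 rose and 4 fell, and the list did not pass. D14 rose 2.45-fold (log2 1.30 ± 0.25).

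For PA64s roots limma called 1143 probe sets, 597 higher and 546 lower, and 552 without sufficient replicate 2 and 744, 604 and 672 without deficient replicates 1, 2 and 3. Across root probe sets, LYP9 shared 406 higher and 265 lower calls with 9311 (23.4 and 12.4 expected) and 342 and 255 with PA64s (12.5 and 7.45 expected). The parents shared 315 and 177 (19.4 and 14.4 expected), and a direct test between their root responses called 3 probe sets, with 4066 at an unadjusted p under 0.05 and 1716 expected by chance. Across probe sets, the correlation of root responses was 0.729 for 9311 and LYP9, 0.753 for LYP9 and PA64s and 0.488 for the parents. The phosphate and clock lists did not pass in any genotype in root or leaf, nor did the tillering list in root, and in leaf the tillering list had too few measured genes to test.

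**Figure D2:**
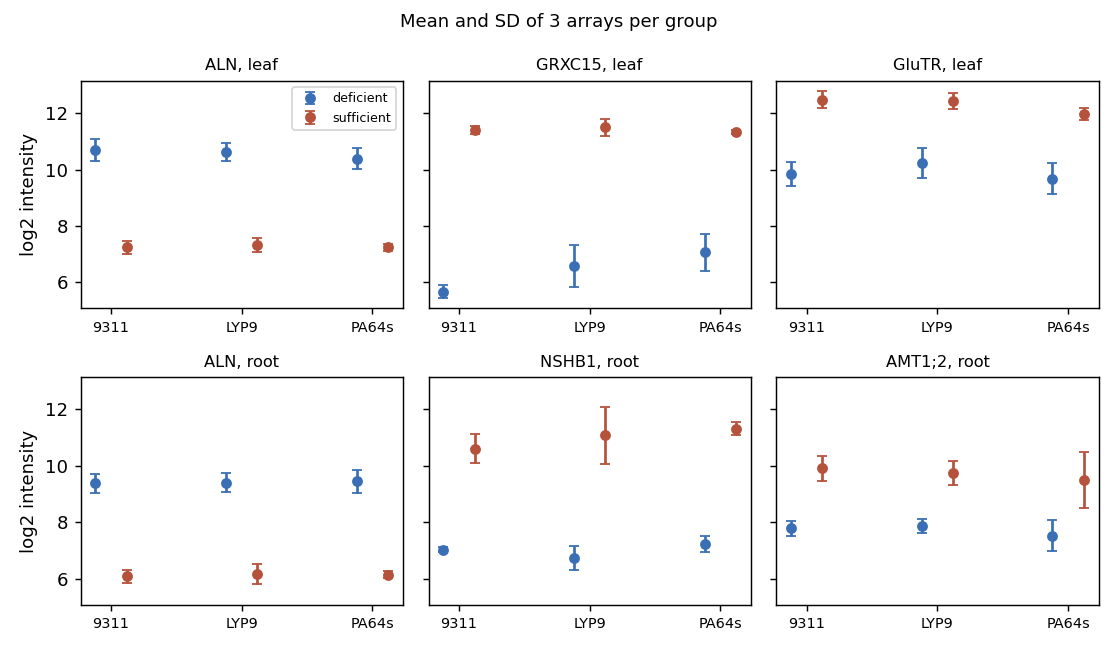
Log2 intensity of 5 named genes by genotype in deficient (blue) and sufficient (red) leaf and root, as the mean and SD of 3 arrays per group. ALN fell in both tissues, from 10.69 to 7.25 in 9311 leaf and from 9.38 to 6.08 in 9311 root.

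The parental comparison asks which transcripts differed between 9311 and PA64s whatever the nutrient state. In leaf, TPP7 (LOC4346885), a trehalose phosphate phosphatase gene, was higher in 9311 by log2 5.00 ± 0.11 (adjusted p = 3.21e-15) with 1 probe set, and by 2.18 with its other. TAC1 (LOC4347655), which sets tiller angle, was higher by log2 2.43 ± 0.11 (adjusted p = 2.75e-11). The zinc transporter ZIP1 (LOC4342782) and the silicon channel NIP2;2 (LOC4340558) were 4.81-fold and 4.44-fold higher. SDH3-2 (LOC4343404), a subunit gene of succinate dehydrogenase, was at log2 -3.31 ± 0.21 in 9311 against PA64s, and AGO18 (LOC4343201), an Argonaute gene of antiviral defence, at -2.23 ± 0.16. PP2C62 (LOC4343331) was called higher by 1 probe set, at 8.71 ± 0.64 log2 units in sufficient 9311 leaf and 1.73 ± 0.76 in PA64s (SD, n = 3). The latter is near the floor, so no fold is given, and the other probe set differed by log2 -0.29 and was not called.

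Of 22 aquaporins 6 were higher in 9311 leaf and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.00302, and adjusted p = 0.592 with an estimated correlation), with TIP1;2 at log2 1.55 ± 0.14. These counts take 1 probe set per gene. A probe set of the aquaporin gene PIP2;1 (LOC4343122) was called lower in 9311 leaf, a call lost without any of 6 arrays (log2 -0.9976 to -0.8568). Of 6 WRKY factors 3 were lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.592 with an estimated correlation), such as WRKY51 (LOC4335388) at log2 -1.19 ± 0.13. limma called 4072 probe sets, 1863 higher and 2209 lower in 9311.

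In root the parents again differed at TPP7 (log2 3.59 ± 0.31 with 1 probe set and 1.61 with the other), SDH3-2 (log2 -3.04 ± 0.14) and AGO18 (log2 -1.75 ± 0.28), and at BURP16 (LOC4348595), 9.75-fold higher in 9311. The iron transporter IRT2 (LOC4333667) was higher by log2 2.56 ± 0.27, and OC-X (LOC4335551), a cystatin gene, 5.92-fold lower (log2 -2.57 ± 0.17, adjusted p = 5.39e-09). Of 44 cell cycle and replication genes 8 were lower and 1 higher in 9311 (19 and 3 adjusted over the list alone; adjusted p = 0.0114, and adjusted p = 0.94 with an estimated correlation). The D-type cyclin CYCD5-3 (LOC4331985) was at log2 -1.24 ± 0.10 and ORC5 (LOC4334180), of the origin recognition complex, at -1.32 ± 0.12, while ORC2 (LOC4331860) of the same complex was at 0.91 ± 0.08. Of 23 aquaporins 4 were higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.0114), of 6 clock genes 3 lower and 0 higher (3 and 0; adjusted p = 0.032), and of 23 cytosolic ribosomal protein genes 2 higher and 0 lower (0 and 0; adjusted p = 0.032). All of these root lists had adjusted p = 0.94 with an estimated correlation. limma called 4576 probe sets, 2109 higher and 2467 lower, and the count was 7010 without PA64s sufficient replicate 1 and 3049 without PA64s deficient replicate 2. Leaf and root shared 553 probe sets higher in 9311 and 957 lower, where 94.4 and 131 were expected by chance among the 30464 kept in both tissues.

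The hybrid comparison asks which transcripts in LYP9 departed from the mean of its parents, in the state the labels call heterotic and in the other. In nutrient-sufficient leaves, limma called 277 probe sets above the log2 mid-parent and 5 below. No gene met the naming rule there. In every mid-parent contrast its separation step sets the LYP9 arrays against those of both parents together. It therefore passes over probe sets at which LYP9 lies between its parents. The calls above went with large parental differences: 274 of them (98.9%) also differed between 9311 and PA64s, with a median parental difference of 18-fold, against 11.9% of all probe sets. PA64s was the higher parent for 198 and 9311 for 79. Against the mean of the parents on the linear scale 0 of the calls above remained and 2 below were called, with 708 probe sets at an unadjusted p under 0.05.

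The 5 probe sets below the mid-parent, named after their values were seen, were HSF6 (LOC4348646), a heat shock factor gene, at log2 -1.21 ± 0.25 (its other probe set was at 0.04 and not called), LOC4336657 at -2.36 ± 0.41, LOC4327742 at -1.03 ± 0.19 and a pair with no listed gene at -1.70 ± 0.30 and -1.73 ± 0.34. HSF6 was also called below in deficient leaf (-1.42 ± 0.25, adjusted p = 0.00681). The first of the pair was also called below in both root states (-2.87 and -2.96). It and LOC4336657 were also called in sufficient leaf on the linear scale (-2.52 and -3.88). In sufficient leaf the replicate numbers paired the samples of this comparison. With replicate as a block 312 probe sets were called, 303 above and 9 below, of which 279 were also called without it. With a block within each nutrient state 323 were called. Only 2 probe sets lay outside the parental range, both above it: LOC4339882, by log2 0.50 against 9311 and 0.49 against PA64s, and a probe set with no listed gene, by 0.95 and 1.25. Both were named after their values were seen, and with replicate as a block 4 lay outside. This count was 0 without 9311 replicate 1 or without LYP9 replicate 1.

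In nutrient-deficient leaves LYP9 lay below the mid-parent at the ammonium transporter gene AMT3;2 (LOC4334717), with 7.91 ± 0.30 log2 units against 9.17 ± 0.30 in 9311 and 9.50 ± 0.75 in PA64s (SD, n = 3). Its difference from the mid-parent was log2 -1.42 ± 0.31 (adjusted p = 0.0389), and it lost its call on leaving out any array except 9311 replicate 2 or PA64s replicate 3, at values from -1.53 to -1.25, and with 1 probe set per gene (adjusted p = 0.0569). The factor gene OsbZIP49 (LOC4341530) was at log2 -0.77 ± 0.13 (adjusted p = 0.004), and at -0.69 and not called without LYP9 replicate 2. The kinase gene BIMK2 (LOC4328223), at log2 -0.94 ± 0.20, and OPR5 (LOC4340485), at -0.60 ± 0.14, lost their calls on leaving out any array except PA64s replicates 1 and 3 for BIMK2 (-0.88 without 9311 replicate 3) and PA64s replicate 3 for OPR5 (-0.67 to -0.51). With 1 probe set per gene neither was called (adjusted p = 0.052 and 0.0703), and OPR5 was not called with the replicate block (0.0633), no filter (0.0678), quantile normalization (0.0992) or all 36 arrays (0.829). TPP7, from the starch and sucrose list, was above the log2 mid-parent by log2 1.53 ± 0.13, but at -0.03 against the mean on the linear scale, and its other probe set was at 0.49 and not called.

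By list in these leaves, chlorophyll synthesis was higher in LYP9 than the mid-parent by a median of log2 0.33, with 0 of 9 members called (1 higher adjusted over the list alone; adjusted p = 0.000346, and adjusted p = 0.478 with an estimated correlation). Light-harvesting and photosystem genes had a median of log2 0.24, with 0 of 8 called (0 adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.478 with an estimated correlation). Of 27 starch and sucrose genes 1 was higher (1 adjusted over the list alone; median 0.09, adjusted p = 0.0332, and adjusted p = 0.478 with an estimated correlation). Of 23 cytosolic ribosomal protein genes 0 were called (0 adjusted over the list alone; median -0.13, adjusted p = 0.0288), and of 11 defence genes 0 (2 lower adjusted over the list alone; median -0.06, adjusted p = 0.038). Both had adjusted p = 0.722 with an estimated correlation. limma called 282 probe sets above the mid-parent and 29 below, and 0 on the linear scale, where 1526 had an unadjusted p under 0.05 and 1716 were expected by chance. On that scale AMT3;2 and OsbZIP49 hardly moved, at log2 -1.43 and -0.77, and lost their calls through the adjusted p, which was 0.224 and 0.0857. Of the 282, 99.3% also differed between the parents, and 225 were also called above in sufficient leaves, with 2.28 expected.

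Outside the parental range in deficient leaves lay 5 probe sets, named after their values were seen except OsbZIP49. Below both parents were OsbZIP49, by log2 -0.66 against 9311 and -0.88 against PA64s, LOC4327925 (-0.82 and -0.88), LOC4324077 (-0.76 and -0.70) and LOC4331468 (-2.57 and -3.92). A probe set with no listed gene lay above both, by 1.18 and 1.60. Left-out arrays moved this count to 0 without LYP9 replicate 2, 1 without LYP9 replicate 1 or 9311 replicate 1 or 3, 8 without PA64s replicate 3 and 14 without LYP9 replicate 3.

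**Figure D3:**
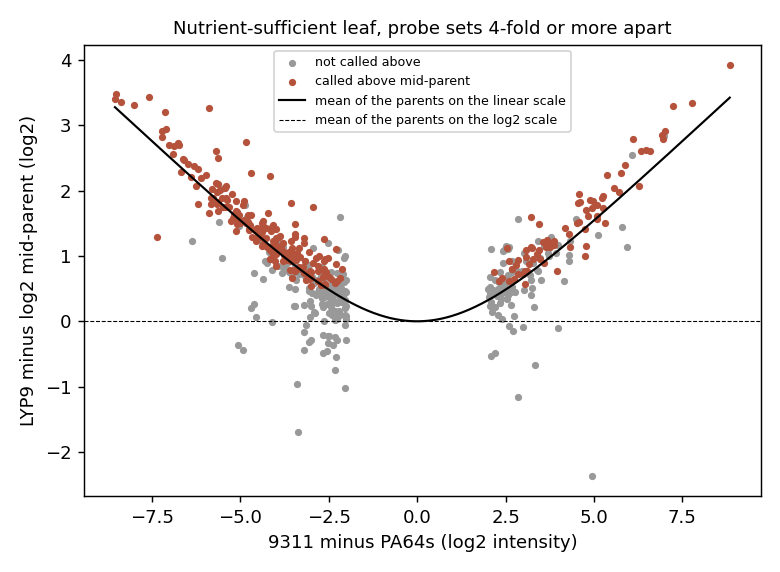
LYP9 minus the log2 mid-parent against 9311 minus PA64s (log2) for the 568 probe sets at least 4-fold apart between the parents in nutrient-sufficient leaf, with the value that the mean of the parents on the linear scale would give drawn as a curve. The points lie at a median distance of 0.18 log2 units from that curve, with a median signed deviation of 0.05.

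In root the pattern was alike. LYP9 had 244 probe sets above the mid-parent and 3 below in the sufficient state, and 173 and 3 in the deficient state, of which 166 above were shared (1.23 expected). All of these calls above also differed between the parents (100%), against 13.3% of all probe sets. On the linear scale 0 stayed above and 3 were called below in each state, with 505 and 730 probe sets at an unadjusted p under 0.05. The 3 below the log2 mid-parent, named after their values were seen, were LOC4340413 (log2 -0.73 ± 0.14 and -0.67 ± 0.14 in sufficient and deficient roots) and a pair with no listed gene, at -2.87 ± 0.22 and -2.96 ± 0.22 for the first and -0.64 ± 0.14 and -0.99 ± 0.14 for the second. The first of this pair is also the first of the pair named in sufficient leaf (-1.70). On the linear scale the first of the pair was called in both root states (-4.60 and -4.90), the second in deficient root (-1.16), and LOC4340413 in neither. limma called 0 probe sets outside the parental range in either state, with 26 and 96 beyond both parents at unadjusted p under 0.05. With array weights these counts were 55 and 4.

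In sufficient roots 8 gene lists passed camera against the mid-parent at the preset correlation, with 0 members called over all genes or adjusted over the list alone. None passed otherwise: defence and auxin had adjusted p = 0.133 with an estimated correlation, and the other lists adjusted p = 0.476 with an estimated correlation. At the preset correlation, lower in LYP9 were 13 defence genes (median log2 -0.39, adjusted p = 3.27e-05), 25 jasmonate genes (-0.24, adjusted p = 4.37e-05), 55 auxin response genes (-0.08, adjusted p = 0.00215), 6 WRKY factors (-0.45, adjusted p = 0.0158), 20 nitrogen genes (-0.08, adjusted p = 0.0444), and 6 photosystem and 6 root-enriched genes (-0.33 and -0.19, adjusted p = 0.0488). Higher were 7 metallothioneins (0.23, adjusted p = 0.0158). In deficient roots no list passed.

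The direct test of the study's contrast is whether the deviation of LYP9 from the mid-parent differed between the nutrient states. With limma 0 of 34316 probe sets were called in leaf, where 622 had an unadjusted p under 0.05, 1716 were expected by chance and the smallest adjusted p was 0.949. In root 0 were called, 504 had an unadjusted p under 0.05 and the smallest adjusted p was 0.396. Both unadjusted counts lay below the 1716 expected, so small p-values were rarer here than chance alone would give. The 0 calls are therefore weak evidence that no probe set differed. The alternative limma fits gave 0 except 1 in leaf with all 36 arrays and 1 in root with array weights, and leaving out PA64s deficient replicate 3 in leaf gave 1. In root 1 was called without LYP9 sufficient replicate 1 and 1 without PA64s deficient replicate 2. Simulated differences of log2 1 were called in 48% of cases in leaf and 52% in root. Those runs planted 200 changed probe sets with noise independent between arrays, so these shares may be too high where few probe sets change. They held no noise shared by arrays of the same replicate number. In leaf 33 of 45 same-number correlations were over 0.1, so the shares need not hold for these arrays.

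Some gene lists passed camera in this test at the preset correlation, with 0 members called over all genes or adjusted over the list alone, and none passed with an estimated correlation (lowest adjusted p = 0.238). In leaf, LYP9 relative to the mid-parent was lower in the sufficient than the deficient state for 9 chlorophyll synthesis genes by a median of log2 -0.29 and for 8 photosystem genes by -0.24, both at adjusted p = 0.000468, and adjusted p = 0.792 with an estimated correlation. For 6 clock genes the median was -0.18 (adjusted p = 0.0238, and adjusted p = 0.856 with an estimated correlation). In root, 17 iron genes were at -0.26, 9 ethylene genes at -0.19 and 6 WRKY factors at -0.36, each at adjusted p = 0.0179. Defence, jasmonate, auxin response and potassium transport genes were at -0.19, -0.15, -0.07 and -0.12 and metallothioneins at 0.33, each at adjusted p = 0.0443. With an estimated correlation, ethylene had adjusted p = 0.238, jasmonate adjusted p = 0.749 and the other root lists adjusted p = 0.439.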

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

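Of the tests in this part, the comparison with probe sets of 4-fold nutrient responses, the contrasts between leaf and root, those between the parents' nutrient responses and the splits within replicate numbers were chosen only after results were seen. The bound for the clock gene test was tightened after its value was known.

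The mean nutrient response of the 3 genotypes differed between leaf and root at 5212 of 30464 probe sets, 3452 with the higher response in leaf and 1760 with the lower. This split was not repeated after median centring. Median responses over all probe sets were log2 0.06 to 0.07 in leaf and -0.01 to 0.05 in root, by genotype. The mean deviation of LYP9 from the mid-parent differed between the tissues at 55 probe sets. The nutrient responses of 9311 and PA64s differed at 6 probe sets in leaf and 3 in root. With a listed gene among them were LOC4350133 (log2 difference 3.34), LOC4335838 (2.19) and LOC4336903 (-1.40) in leaf, and LOC4326140 (-1.48) in root, all named after their values were seen.

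For the LYP9 deviation between the nutrient states, some gene lists passed camera at the preset correlation, with 0 members called, and none passed with an estimated correlation, where the lowest adjusted p was 0.238. They were, in leaf, chlorophyll synthesis (median log2 difference -0.294), light harvesting and photosystems (-0.239) and the clock (-0.176). In root they were WRKY factors (-0.361), iron (-0.257), ethylene (-0.19), defence (-0.186), jasmonate (-0.151), potassium transport (-0.121), auxin response (-0.0707) and metallothioneins (0.332).

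LYP9 was above the log2 mid-parent far more often than below it in all 4 comparisons. With the parents averaged on the linear scale 0% of the higher calls were left, so the choice of scale is a candidate explanation for the excess. Data were also simulated with the hybrid at the linear mean. There limma called 1861 of 2000 probe sets with parents 16-fold apart above the log2 mid-parent, and 0 above the linear one. Both outcomes follow from how those data were built, so they are no evidence about the real arrays. Poor binding of a parent's transcript to the probes may add large parental differences to the excess. In 24 of 91 entries (26.4%) another probe set of the same gene showed the parental difference. It had to have the same direction and 50% of the size or more. For nutrient responses of 4-fold or more the share was 75.9% of 166. The 166 were chosen by the call and size of that response. The 91 were chosen by a call above the mid-parent, with no minimum parental difference. The gap between the shares thus cannot be assigned to probe binding. An entry is a probe set in 1 tissue (for nutrient responses also 1 genotype), and the 91 hold 64 distinct pairs of probe sets. The simulation also gave 51 calls below the log2 mid-parent, all at probe sets simulated with no difference. It gave 1905 calls above, against 173 to 282 in the real comparisons, so the 51 cannot be set against the real calls below. False calls among those few, and a biological difference between hybrid and parents, stay open as untested.

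Leaf arrays with the same replicate number deviated together from their group means, with a mean correlation of 0.224 against -0.114 for different numbers. After quantile normalization, which gives all arrays the same distribution of values, the same-number value was 0.222. That argues against differing distributions as the source. A constant scale factor per array cannot alter such a correlation, so for it the outcome was fixed in advance. Time of day may be involved and cannot be told apart from other shared conditions. The 6 clock genes stood at the 49.8th percentile of random lists for the difference between arrays numbered 3 and 1. That met the bound first written for arguing against time of day, but lay within its resampling spread. It did not meet the tightened bound. LHY (LOC4344703) was the only clock gene called between them, at log2 -0.96 (adjusted p = 0.000651), among 5384 probe sets called. No biological explanation was tested.

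More probe sets were higher than lower in nutrient-sufficient leaves, 67.2% of calls over the 3 genotypes. After median centring 45.8% were higher, so array-wide intensity scaling could account for some or all of the excess. Centring moved the median change of all probe sets past 0. It went from log2 0.0577 to -0.0594 in 9311, 0.0668 to -0.0286 in LYP9 and 0.0703 to -0.0241 in PA64s. The 45.8% may thus overstate the part of scaling. A true rise of many transcripts with fertiliser would be removed by centring too, and stays open as untested.

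Other splits of the same arrays were counted for each result. For the nutrient contrasts, 3 arrays against 3 give 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, gave as many calls: the real counts were 4093, 3037 and 2652 in leaf for 9311, LYP9 and PA64s, with highest other counts of 0, 0 and 1, and 2021, 1188 and 1143 in root, with 0, 3 and 7. For 9311 against PA64s only the real split, 1 of 100, gave as many calls in each tissue, a share under 0.05. The counts were 4072 against a highest other of 337 in leaf and 4576 against 2175 in root. A chance assignment of these arrays can thus be excluded. The labels do not give the source of the replicates, so a chance difference between barrels or plants cannot.

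For LYP9 against the mid-parent, the splits did not exclude chance in sufficient leaf, where 8 of 100 gave 282 calls or more (highest other 1677). Nor did they in sufficient root, with 6 of 100 for 247 (9429). The calls above recurred in other arrays, which argues against chance for them as a set. Among probe sets kept in both tissues, sufficient leaf had 203 and sufficient root 209. They shared 145, with 1.39 expected and 0 in the opposite direction. In leaf the 2 states shared 225, with 2.28 expected. Such sharing does not tell the scale of the mid-parent from biology. In sufficient leaf the replicate numbers pair the samples. Of 100 splits that exchange genotypes within each number, 13 gave the 312 calls of the replicate block fit or more (highest other 2592). These splits did not exclude chance in that fit either. Of the 12 others, 8 put a single parent in the place of LYP9, and splits with mixed genotypes there reached 639. In deficient leaf 2 of 100 splits gave 311 calls or more (highest other 1248), a share under 0.05. In deficient root 2 of 100 gave 176 or more (583). In each, the 1 other split as large put a single parent in the place of LYP9. Such shares argue only against interchangeable genotypes. The parents themselves differ, so these splits cannot show whether LYP9 departed from the mid-parent. The splits with several times the real count point to a structure of the samples: the largest put all 3 9311 arrays in the place of LYP9 in both leaf states, 3 PA64s arrays in deficient root, and 1 LYP9 and 2 PA64s arrays in sufficient root. For probe sets outside the parental range, 2 of 100 splits gave 5 or more in deficient leaf (highest other 605), a share under 0.05. These splits also mix genotypes that differ, so they cannot show that the 5 are not false calls. In sufficient leaf 4 of 100 gave 2 or more (647), but 10 of 100 splits within replicate numbers gave the 4 of the replicate block fit or more (828), so chance is not excluded. Of the 9 others there, 8 put a single parent in the place of LYP9, among 11 such splits drawn, and splits with mixed genotypes reached 4. Where the real count was 0, all 100 of 100 splits give as many by construction, which decides nothing. This holds outside the range in sufficient root (highest other 1642) and deficient root (202), and for the change in LYP9 deviation in leaf (2120) and root (703).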

How the results depend on the processing

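Replicate numbers paired the samples in 2 of 18 results, LYP9 against the mid-parent (312 calls with a replicate block, 282 without) and outside the parental range (4 and 2), both in sufficient leaf. The block within each nutrient state, chosen after seeing the data, gave 323 and 3. The pairing rule needed every same-number correlation over 0.1, and the main fits held no replicate term in any result. A shared replicate effect is thus not confined to those results. For the change of LYP9 deviation in leaf, 33 of 45 same-number correlations were over 0.1. With 3 arrays per group and background signal not analysed here, weak signals are limited by the arrays' number. Leaving out an array, 1125 of 1311 values of named genes kept their call and direction and 186 lost the call. Under a 2-fold minimum 37 of 179 lost it, with all 36 arrays 14, with no filter 9 and with quantile normalization 9. With array weights 0 of 179 did. On the linear mid-parent TPP7 reversed, from log2 1.53 to -0.03416, by the construction of that mean, and 4 of 5 values lost the call. Where no construction is named below, the cause was not tested.

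Counts that moved by over 1.5 times are grouped by setting. With the replicate block, PA64s leaf gave 4208 and outside the range gave 4 in sufficient and 12 in deficient leaf. The stricter filter, which tests fewer probe sets, gave 1 and 2 outside the range in leaf and 159 and 110 for the root mid-parent. Median centring and the trend and robust options each gave 1 outside the range in sufficient leaf. All 36 arrays gave 4072 for PA64s leaf, 4 and 9 outside the range in leaf and 1 for the leaf deviation. Array weights gave 11313 for 9311 leaf, 5368 for PA64s leaf, 7194 for the leaf parents, 664 for the deficient leaf mid-parent and 118 outside the range there. In root they gave 5361, 4641 and 8378 for 9311, LYP9 and PA64s, 15831 for the parents, 496 for the sufficient mid-parent, 55 and 4 outside the range and 1 for the deviation.

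A 2-fold minimum, which can only remove calls, gave 1259, 991 and 910 for 9311, LYP9 and PA64s in leaf, 1264 for the parents, 202 for the deficient mid-parent and 0 and 2 outside the range. In root it gave 529, 480 and 612, and 1013 for the parents. With 1 probe set per gene, which tests fewer, 9311 leaf gave 2220, PA64s leaf 1743, the leaf parents 2099, the leaf mid-parent 81 and 82, outside the range 1 and 3, the root parents 2190 and the root mid-parent 77 and 62. The linear mid-parent gave 2 and 0 in leaf and 3 and 3 in root. Outside the range in sufficient root were 1 with no filter and 2 with quantile normalization. With an estimated correlation 0 of 53 gene list calls held.

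Leaving out 1 array in turn gave ranges of 1830 to 3932 in leaf for 9311, 1364 to 3520 for LYP9 and 1160 to 2300 for PA64s, and in root 303 to 3738, 319 to 1515 and 552 to 1066. The root parents ran from 3049 to 7010. Outside the range ran from 0 to 3 in sufficient leaf, 0 to 14 in deficient leaf and 0 to 7 in deficient root, where LYP9 replicate 3 gave the 7. The deviation ran from 0 to 1 in each tissue. In sufficient leaf, outside the range was 0 without 9311 or LYP9 replicate 1, and 1 without 9311 replicate 2 or 3, LYP9 replicate 2, or PA64s replicate 1 or 2.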

Other observations

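Some nutrient responses went in opposite directions in leaf and root. The genes below were chosen after their values were seen, and each value is the mean log2 response of the 3 genotypes (SE). Among 149 probe sets of 130 list genes that differed between the tissues, 24 were called in opposite directions, and over all 5212 probe sets that differed 385 were. The ammonium transporter gene AMT1;2 (LOC4330008) was at -0.68 ± 0.10 in leaf and 2 ± 0.23 in root (adjusted p of the difference 3.32e-08), and AMT2;1 (LOC4339064) at 0.65 ± 0.15 and -0.93 ± 0.12 (adjusted p = 1.76e-06). NAAT1 (LOC9267778), of iron chelator synthesis, was at -1.48 ± 0.25 and 1.79 ± 0.20 (adjusted p = 1.07e-07), and the iron regulator gene IRO3 (LOC4332972) at -1.54 ± 0.24 and 0.92 ± 0.16. The ascorbate peroxidase gene APx7 (LOC4335896) was at -1.51 ± 0.08 and 0.51 ± 0.11, and the phosphate transporter gene Pht1;4 (LOC4335115) at -1.21 ± 0.26 and 1.47 ± 0.29. In the phenylpropanoid pathway 4CL3 (LOC4328485) was at 1.36 ± 0.20 and -0.40 ± 0.11.

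Lists that passed camera in none of the planned contrasts were cell wall expansion, cytokinin, fermentation and hypoxia, heat shock and chaperones, oxidative stress and detoxification, phosphate starvation, sugar transport, and tillering and strigolactone. Their lowest adjusted p was 0.0543, for sugar transport in the change of LYP9 deviation in root.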
